A study of Mus musculus with 8 samples.

How the data were processed

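Gene expression was measured in mouse cells with 8 1-colour Affymetrix arrays of biotin-labelled total RNA. The labels put 3 arrays in the group of parthenogenetic stem cells (PSC), 2 in embryoid bodies made from PSC (EB_PSC) and 3 in embryonic stem cells (ESC). The deposited table holds 45101 probe sets, and all 8 of its value columns matched a sample label.

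The deposited values are on the log2 scale and were made with RMA in Bioconductor, per the submitters' processing notes and the labels. Versions, background settings and whether the 8 arrays were normalized together are not given in the sources used here. The log2 scale was taken from the values themselves. They ran from 2.56 to 14.9, with array medians between 5.39 and 5.47, and were not centred per gene. No further normalization was applied. RMA brings the arrays to nearly the same distribution of values, so a shift of most transcripts in 1 direction would not be visible in them, and differences of dim probe sets are compressed towards 0. Where a compared group had a mean below 5.44, the limit of the filter on dim probe sets, the size of a difference is a lower bound and no fold is given. The number of arrays limits the precision, most of all for the 2 embryoid body arrays.

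Probe sets were named through the platform annotation supplied with the table. It gave 1 gene symbol to 34958 probe sets, several to 932 and none to 9211. Of the 64 control probe sets, 13 carry 1 gene symbol and were kept under it. Entrez identifiers matched 34754 of the single-gene probe sets to RefSeq genes of the assembly GRCm38.p6, which updated 0 symbols. That assembly served only for names, chromosomes and the order of neighbouring genes, since no build is settled for the arrays, and no coordinates are given. Each of 18194 genes was represented by its probe set with the highest mean over all arrays. Probe sets that name several genes or none were left out of the gene tests.

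Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes) in a single fit of all 8 arrays with the group as the only term, which left 5 residual degrees of freedom and added 8.07 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 18194 genes, and a gene was called at an adjusted p below 0.05. Differences are given in log2 units as the difference ± its standard error from the fit. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with a correlation estimated per list, adjusted over 31 lists. These were 30 lists from textbook knowledge and the genes of chromosome X. With an estimated correlation camera uses only the 5 residual degrees of freedom of the fit, which raises p also for lists of low correlation. The 30 lists name 494 different genes, of which 452 had a probe set of their own and 42 were not analysed here. A list symbol that had become a synonym was matched through RefSeq.

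The groups, the main model, the lists, the rule for named genes and the alternatives were set before the data were examined, apart from the removal of chromosome 12, which was chosen after seeing the data. In each of the main comparisons the rule names the 8 largest rises and the 8 largest falls among called genes whose arrays do not overlap between the groups, and up to 4 called members of each list described, by size of the difference. It also names 30 fixed genes, of which 28 were measured and 2 not analysed here. The alternatives comprised a repeated quantile normalization, cyclic loess, a filter on dim probe sets, the mean of all probe sets of a gene, removal of probe sets whose identifiers mark possible cross-hybridisation (ending in _x_at or _s_at), a fit of the compared groups alone, a trended and robust variance prior, array weights, the replicate number as a block, each array left out in turn, removal of chromosomes X and Y, a threshold of 2-fold, and a test of every probe set.

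RNA quality was followed as the difference between the 3' and 5' control probe sets of Gapdh and Actb on each array, with exact two-sided permutation tests. Random gene sets (10000 draws) were matched on mean signal. Order along chromosomes was examined for genes with a mean above 8 in PSC and ESC, with a running median of 21 genes. For the chromosome 12 segment the differences were shuffled 1000 times among autosomal genes of like signal, and the segment was chosen again without each ESC array. These steps and the figures used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.

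The gene test was tested on simulated data for 18194 genes with the real means and spreads and 200 changed genes. For PSC against ESC it called 38% of genes changed by 0.5, 93% of those changed by 1 and 100% of those changed by 2 log2 units, with 9 unchanged genes called. For embryoid bodies against PSC the shares were 12%, 74% and 100%, with 6 unchanged genes called. In the real comparisons 3782 and 7995 genes passed, which makes the adjusted threshold less strict, so these shares may understate the recovery there. In a simulated table for PSC against ESC with 1 shifted list, the fibroblast list, camera called that list (adjusted p = 3.32e-19, and 0.00593 with an estimated correlation) and 0 others. Its genes varied independently, while the real macrophage list had an estimated correlation of 0.453. The simulation therefore does not show how often camera calls lists falsely in the real data.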

Results

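The series, from a study of heart tissue engineered from parthenogenetic cells, measured transcript levels in 3 kinds of mouse culture. PSC (3 arrays) are parthenogenetic stem cells of the strain C57BL/6, isolated on day 6 from blastocysts that grew from oocytes activated with strontium chloride, so that they carry maternal genomes only. EB_PSC (2 arrays) are embryoid bodies, free aggregates in which PSC differentiated for 15 days. ESC (3 arrays) are embryonic stem cells of the line R1, grown on mouse embryonic fibroblast feeders with leukemia inhibitory factor. All values are deposited log2 RMA values. Pearson's r across probe sets, which are not independent replicates, was 0.994 to 0.995 between PSC arrays, 0.991 to 0.995 between ESC arrays and 0.992 between the embryoid body arrays. It was 0.978 to 0.986 between PSC and ESC arrays and 0.934 to 0.943 between embryoid body and PSC arrays. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

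The first comparison asked how undifferentiated PSC differ from ESC that have both a maternal and a paternal genome. The groups also differ in cell line and sex chromosomes. Strain may differ too, since it is named here only for PSC, and feeder use is given only for ESC. Genome origin is therefore confounded with these in every difference between PSC and ESC. Genes that are read from the paternal chromosome stood among the largest differences. Peg3, a zinc finger gene read from the paternal allele, was 23.9-fold lower in PSC (5.71 ± 0.25 against 10.29 ± 0.10, SD, n = 3 each) and Mest, another paternally expressed gene, was 22.3-fold lower (6.41 ± 0.45 against 10.89 ± 0.20). The Y-linked gene Eif2s3y, which encodes a translation initiation factor subunit, was lower in PSC (4.74 against 10.31), and Olig1, a transcription factor gene of the oligodendrocyte lineage, was higher (9.69 against 3.96). Both were below the limit for dim probe sets in the lower group, so their differences are lower bounds. The maternally expressed growth regulator Grb10 was 6.22-fold higher.

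Among the paternally expressed imprinted genes, 13 of 26 measured were lower in PSC, 2 were higher and 11 did not pass the test. With p adjusted over the list alone, 14 were lower and 2 higher. The median difference was -0.45 log2 units (-1.11 without dim probe sets), and the list fell relative to other genes (camera adjusted p = 3.19e-08; adjusted p = 0.17 with an estimated correlation). Peg3 fell by 4.58 ± 0.14 (limma adjusted p = 5.44e-10), Mest fell by 4.48 ± 0.19 (8.88e-09), Peg10 fell by 3.63 ± 0.17 (1.59e-08) and Impact fell by 3.42 ± 0.15 (8.88e-09). Igf2, a fetal growth factor, fell by 0.86 ± 0.14 (0.000825), a call that was lost with the mean of all its probe sets (-0.34, adjusted p = 0.112, against a range of 0.000332 to 0.112 over the alternatives). Snrpn fell by 0.44 ± 0.14 (0.0381), a call that was lost without any single 1 of the 6 PSC and ESC arrays (adjusted p between 0.0515 and 0.129, within a range of 0.00537 to 0.129 over the alternatives). Plagl1, a zinc finger gene, fell by 3.31 ± 0.20 (2.33e-07) on an _x_at probe set; without such probe sets its difference was 0.25 (adjusted p = 0.256, the highest of a range from 2.98e-09). The 2 higher genes were the amino acid transporter gene Slc38a4 (1.94 ± 0.14, 8.02e-07) and Sfmbt2 (0.46 ± 0.12, 0.013), whose call was lost without PSC 3 (0.0524) or ESC 3 (0.0647; range 0.000745 to 0.0647). Dlk1 differed by -0.15 ± 0.15 (adjusted p = 0.556). Outside the list, Snhg14, the RNA host gene of small nucleolar RNAs in the Snrpn region, fell by 5.27 ± 0.20 (2.32e-09). On the same arrays the median of fibroblast genes was lower in PSC by -0.62.

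Maternally expressed imprinted genes leaned the other way, with 7 of 25 measured higher in PSC, 3 lower and 15 not past the test. The counts were also 7 and 3 when adjusted over the list alone. Their median was 0.18, and the list rose relative to other genes (camera adjusted p = 0.0134; adjusted p = 0.259 with an estimated correlation). Grb10 rose by 2.64 ± 0.13 (limma adjusted p = 1.72e-08), the placental growth regulator Phlda2 by 1.51 ± 0.14 (8.52e-06), the transcription factor Ascl2 by 1.23 ± 0.15 (0.000115) and the long noncoding RNA Meg3 by 1.10 ± 0.19 (0.00127), although 1 of the Meg3 probe sets ran opposite to the others and the rise was 0.67 without _x_at and _s_at probe sets (0.00109). Rian, a noncoding RNA next to Meg3, rose by 0.82 ± 0.15 (0.00138). Cdkn1c, a cell cycle inhibitor, rose by 0.74 ± 0.19 (0.0135), a call that was lost without PSC 1 (0.0503) or PSC 2 (0.0645; range over the alternatives 0.000858 to 0.0645). Igf2r was at 0.32 ± 0.19 (0.283) and passed the test with the mean of its probe sets (0.47, adjusted p = 0.0327; range 0.0327 to 0.77). Meg3 and Rian lie on chromosome 12, where many genes were higher in PSC; without that chromosome, an alternative chosen after seeing the data, the list had a median of 0.18 and an adjusted p of 0.0524, against a range of 0.00436 to 0.259 over the other alternatives.

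**Figure D1:**
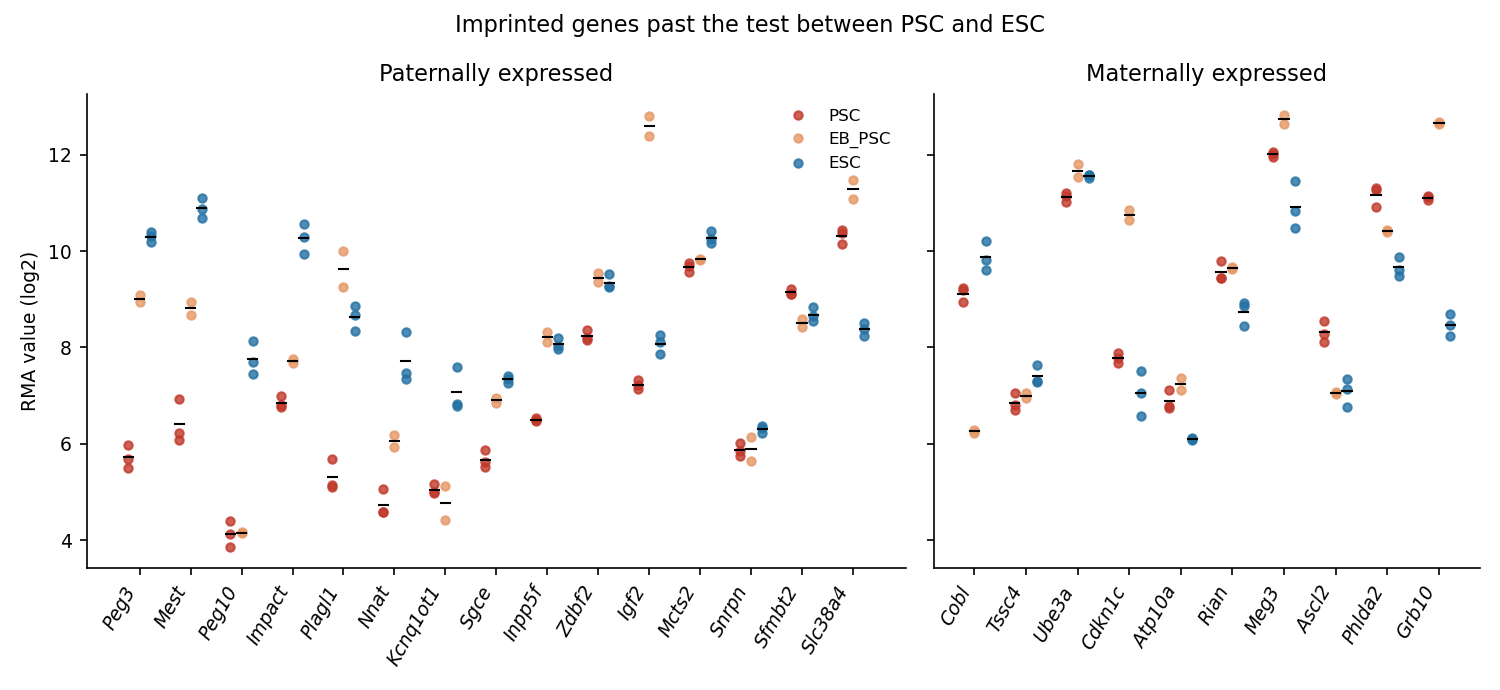
Deposited RMA values (log2) of the imprinted genes that passed the test between PSC and ESC, with 1 point per array, a bar at each group mean, and paternally expressed genes on the left and maternally expressed genes on the right. Peg3 had means of 5.71 in PSC, 9.01 in embryoid bodies and 10.29 in ESC, while Grb10 had means of 11.10, 12.65 and 8.47.

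Genes of the sex chromosomes differed in the same arrays. PSC carry maternal genomes only and hence no Y chromosome, so a lower Y-linked signal in them follows from the design. Of 7 Y-linked genes measured, 3 were lower in PSC, 0 were higher and 4 did not pass the test, with the same counts when adjusted over the list alone (camera adjusted p = 0.0061; adjusted p = 0.184 with an estimated correlation). They were Eif2s3y, which fell by 5.57 ± 0.17 (limma adjusted p = 5.44e-10), Uty, a histone demethylase family member, which fell by 3.67 ± 0.17 (1.07e-08), and Uba1y, which fell by 1.36 ± 0.12 (5.13e-06), or by -3.51 without _x_at and _s_at probe sets (1.2e-09, the lowest of a range up to 0.000107). Kdm5d was dim in both groups (4.40 and 4.07) and differed by 0.33 ± 0.15 (0.144). Of 10 genes of X inactivation or escape from it, 0 were higher and 1 lower, over all genes and adjusted over the list alone, and 9 did not pass the test (camera adjusted p = 0.717; adjusted p = 0.832 with an estimated correlation). The 1 was Xist, the RNA that silences an X chromosome, which fell by 1.41 ± 0.19 (0.000193) on an _s_at probe set. Without such probe sets its difference was 0.06 (0.786, the highest of a range from 6.37e-06).

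Pluripotency genes differed in both directions. Of 31 pluripotency genes measured, 9 were lower in PSC, 6 higher and 16 not past the test, or 12 lower and 6 higher when adjusted over the list alone. The median was -0.23 (camera adjusted p = 0.0166; adjusted p = 0.649 with an estimated correlation). That call was also lost with quantile normalization again (median -0.11, adjusted p = 0.15), with cyclic loess (-0.14, 0.165), with the filter on dim probe sets (0.106) and without ESC 1 (0.0578; range over the alternatives 0.00121 to 0.649). Pou5f1, which encodes Oct4, was at 11.70 ± 0.06 in PSC and 12.31 ± 0.24 in ESC (SD, n = 3 each) and fell by 0.61 ± 0.13 (limma adjusted p = 0.00479). Nanog differed by -0.32 ± 0.11 (0.066), passing the test with the mean of its probe sets (0.0394) and with the trended prior (0.0461; range 0.0394 to 0.207), and Sox2 by -0.26 ± 0.14 (0.248). Zfp42, which encodes Rex1, fell by 2.73 ± 0.12 (1.07e-08), Klf5 fell by 1.56 ± 0.16 (2.43e-05) and the Nodal antagonist gene Lefty2 fell by 1.51 ± 0.15 (1.64e-05), whereas Dppa3 rose by 1.25 ± 0.19 (0.000423).

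Targets of fibroblast growth factor and Erk signalling were lower in PSC for 6 of 12 genes and higher for 2, with 4 not past the test, and 7 were lower and 2 higher when adjusted over the list alone. The median was -0.50, or -0.33 with the mean of all probe sets (camera adjusted p = 0.0134; adjusted p = 0.259 with an estimated correlation), and the call was also lost with the filter on dim probe sets (0.0729; range over the alternatives 0.00561 to 0.259). Myc fell by 2.38 ± 0.19 (limma adjusted p = 2.6e-06), and the transcription factors Etv5 and Etv4 fell by 1.81 ± 0.21 (6.8e-05) and 1.34 ± 0.18 (0.000196). Ier3 rose by 1.10 ± 0.14 (0.000114).

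Fibroblast genes, which cover the feeder cells under the ESC, were lower in PSC for 10 of 17 measured, with 0 higher and 7 not past the test, and for 13 when adjusted over the list alone (camera adjusted p = 2.44e-06; adjusted p = 0.184 with an estimated correlation). The receptor gene Pdgfrb fell by 2.05 ± 0.20 (limma adjusted p = 1.67e-05), S100a4 fell by 1.45 ± 0.27 (0.0018), and the collagen genes Col3a1 and Col1a1 fell by 1.41 ± 0.19 (0.000203) and 1.28 ± 0.24 (0.0021). Basement membrane and parietal endoderm genes were lower for 6 of 14, higher for 1 and not past the test for 7, or lower for 7 and higher for 1 when adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.56 with an estimated correlation). This call was lost with the filter on dim probe sets (0.0764) and without ESC 1 (0.0578; range over the alternatives 0.00467 to 0.56). The collagen IV gene Col4a2 fell by 0.84 ± 0.13 (0.000607) and Col4a1 fell by 0.69 ± 0.12 (0.00129). Epithelial genes were lower for 5 of 14, with 0 higher, 9 not past the test and the same counts when adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.21 with an estimated correlation). They included the keratin gene Krt17, which fell by 1.55 ± 0.18 (6.09e-05), the desmosome gene Dsp, which fell by 1.51 ± 0.14 (7.92e-06), and the adhesion gene Epcam, which fell by 1.08 ± 0.12 (3.22e-05).

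Few heart genes differed between undifferentiated PSC and ESC. Of 30 cardiomyocyte genes 2 were higher, 0 lower and 28 not past the test, with 1 higher when adjusted over the list alone (camera adjusted p = 0.946; adjusted p = 0.97 with an estimated correlation). The 2 were the atrial myosin light chain gene Myl4, which rose by 0.76 ± 0.17 (limma adjusted p = 0.00645; 0.49 with the mean of its probe sets), and Nppb, which rose by 0.49 ± 0.15 (0.0295) and lost its call with the repeated quantile normalization (0.0533) and without PSC 1 (0.106), PSC 2 (0.117), ESC 1 (0.0608) or ESC 3 (0.0989), in a range of 0.00335 to 0.117. The differences were 0.32 ± 0.25 for Myh6 (0.447), -0.31 ± 0.15 for Myh7 (0.181, and 0.0426 with array weights, in a range of 0.0426 to 0.478), -0.30 ± 0.13 for Tnnt2 (0.127) and 0.02 ± 0.20 for Nppa (0.961). Of 19 cardiac transcription factor genes 2 were higher, 1 was lower and 16 did not pass the test, also when adjusted over the list alone (camera adjusted p = 0.922; adjusted p = 0.97 with an estimated correlation). Hopx fell by 1.23 ± 0.14 (4.58e-05) and Isl1 rose by 0.67 ± 0.15 (0.00672). Tbx20 rose by 0.57 ± 0.16 (0.0257), a call that was lost with cyclic loess (0.0576), with the mean of its probe sets (0.118) and without PSC 1 (0.0688), PSC 3 (0.115) or ESC 3 (0.109), in a range of 0.00155 to 0.118. Nkx2-5 and Gata4 both differed by -0.12 ± 0.12 (0.573 and 0.568), and the endoderm gene Afp by 0.03 ± 0.27 (0.956). These estimates leave room for small differences, since only 38% of simulated changes of 0.5 were recovered.

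Over all genes, 3782 of 18194 (20.8%) passed the limma test between PSC and ESC, 1651 higher and 2131 lower in PSC, and 550 of them differed by at least 2-fold (268 higher and 282 lower). The balance turned with another scaling, to 2026 higher and 1870 lower with a repeated quantile normalization and 1974 higher and 1933 lower with cyclic loess. Groups did not overlap for 36.5% of genes, against 10% by chance. The 8 largest rises were Olig1 (5.73 ± 0.19, adjusted p = 9.21e-10), Rgcc (4.36 ± 0.21), Rpgrip1 (3.99 ± 0.15), AI662270 (3.57 ± 0.25), Olig2 (3.53 ± 0.29), Gm21283 (3.17 ± 0.11), the X-linked homeobox gene Rhox5 (3.11 ± 0.14) and Spata5l1 (3.05 ± 0.11). The 8 largest falls were Eif2s3y, Snhg14, Peg3, Mest, Uty, Peg10, Impact and the transporter gene Slc47a1 (-3.40 ± 0.15, 1.07e-08). The count was 2490 without PSC 1 and 5693 with array weights. With the mean of all probe sets in place of the brightest, 31 of 102 called genes, counting named genes and imprinted genes, had a difference smaller by over 1.5 times and 1 a larger one, Uba1y (-2.44). Past the test but smaller were, among others, Peg3 (-2.28), Eif2s3y (-2.79), Uty (-1.79), Impact (-1.43), Plagl1 (-1.12), Kcnq1ot1 (-0.89), Sgce (-0.85), Cobl (-0.36), Xist (-0.40), Rpgrip1 (1.14), Grb10 (1.45) and Meg3 (0.40). So were Klf5 (-0.83), Pdgfrb (-1.13), Col3a1 (-0.84), Col1a1 (-0.73), Dsp (-0.99), Krt17 (-0.81), Epcam (-0.67) and Myl4 (0.49). The call was lost for 9 genes, namely Igf2, Grhl2, Tbx20, Acta2, Tfap2c, H2-D1, Tapbp, Ube3a and Atp10a.

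The second comparison followed PSC through 15 days of differentiation as embryoid bodies. Transcripts of heart muscle rose. Tnnt2, which encodes cardiac troponin T, went from 3.39 ± 0.09 (SD, n = 3) to 8.83 ± 0.31 (n = 2), and Ankrd1, a cardiac ankyrin repeat gene, from 3.67 ± 0.07 to 12.38 ± 0.25. The embryonic globin gene Hbb-y went from 3.13 ± 0.09 to 13.03 ± 0.56, and Afp, a marker of visceral endoderm and fetal liver, from 4.11 ± 0.18 to 10.64 ± 1.04. These 4 genes were below the limit for dim probe sets in PSC, so their rises are lower bounds. Pluripotency transcripts fell, and Nanog fell by 1.92 ± 0.13 log2 units (limma adjusted p = 4.35e-08).

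All 31 pluripotency genes were lower in embryoid bodies, over all genes and when adjusted over the list alone, so 0 rose and 0 did not pass the test. The median was -1.92 (camera adjusted p = 2.14e-16; adjusted p = 0.0819 with an estimated correlation). Esrrb, an orphan nuclear receptor gene, fell by 3.62 ± 0.17 (limma adjusted p = 1.81e-09), Mybl2 fell by 3.31 ± 0.20 (1.62e-08), Klf4 fell by 3.03 ± 0.13 (5.58e-10) and Fgf4 fell by 2.85 ± 0.17 (1.28e-08). Pou5f1 fell by 2.13 ± 0.15 (6.24e-08), Sox2 fell by 1.07 ± 0.16 (0.000106) and Zfp42 fell by 1.68 ± 0.14 (4.14e-07).

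Among cardiomyocyte genes, 24 of 30 rose, 1 fell and 5 did not pass the test, with the same counts when adjusted over the list alone. Their median was 1.82, or 0.97 with the mean of all probe sets (camera adjusted p = 3.4e-13; adjusted p = 0.11 with an estimated correlation). The cardiac actin gene Actc1 rose by 6.53 ± 0.15 (limma adjusted p = 2.41e-12), Tnnt2 by 5.44 ± 0.14 (1.06e-11), and the myosin light chain genes Myl2 and Myl7 by 4.91 ± 0.31 (2.66e-08) and 4.46 ± 0.19 (6.45e-10). Myh7 rose by 4.07 ± 0.17 (4.55e-10), Myh6 by 3.21 ± 0.28 (7.74e-07) and the natriuretic peptide gene Nppa by 2.96 ± 0.22 (1.73e-07). Cardiac transcription factors rose for 13 of 19 genes, fell for 0 and did not pass the test for 6, and 14 rose when adjusted over the list alone (median 0.80, or 1.34 without dim probe sets; camera adjusted p = 6.66e-08; adjusted p = 0.0819 with an estimated correlation). Tbx20 rose by 5.69 ± 0.18 (3.89e-11), Hand2 by 4.97 ± 0.14 (2.3e-11), Myocd by 3.12 ± 0.16 (3.36e-09) and Gata4 by 1.34 ± 0.14 (2.8e-06). Nkx2-5 differed by 0.32 ± 0.14 (0.0766) and passed the test only with cyclic loess (0.0134; range over the alternatives 0.0134 to 0.393).

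**Figure D2:**
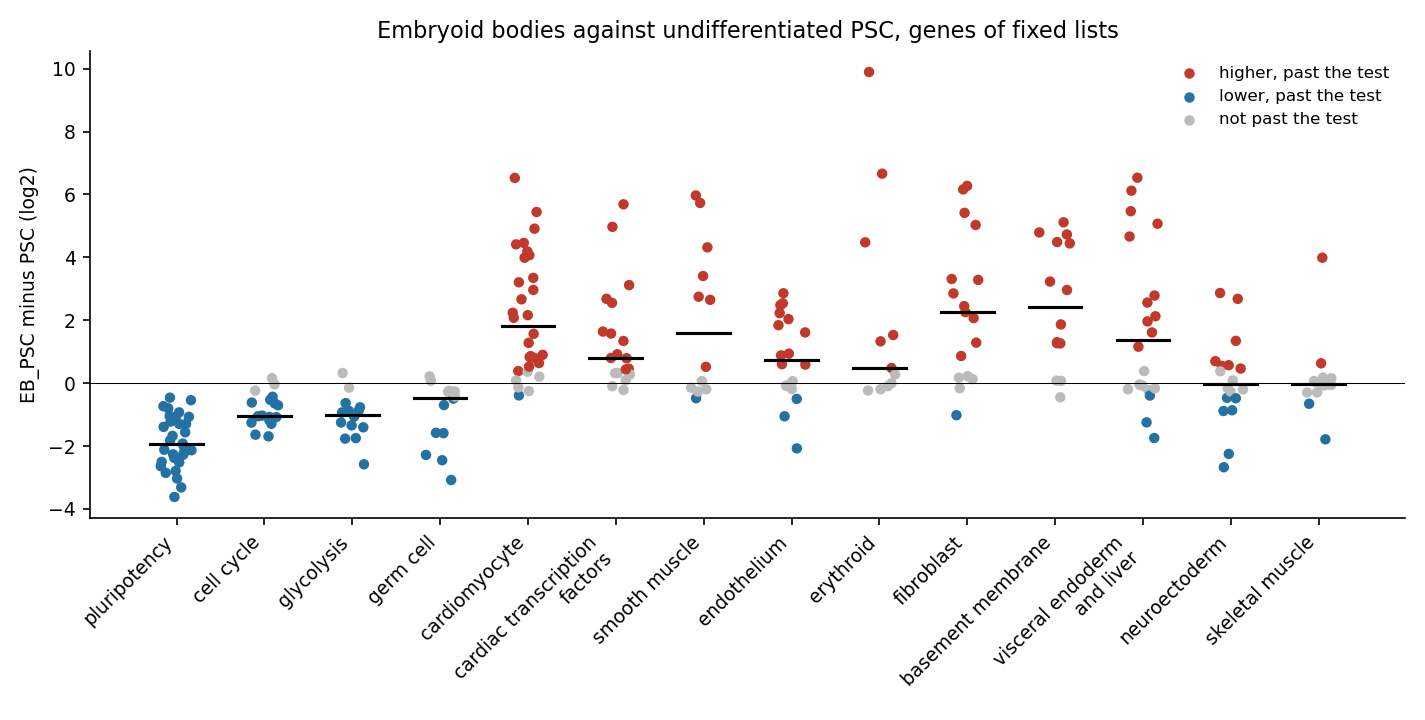
Difference between embryoid bodies and PSC (log2) for the measured genes of 14 fixed lists, with 1 point per gene coloured by the test and a bar at each list's median. The cardiomyocyte list has a median of 1.82 with 24 of 30 genes higher, and the pluripotency list a median of -1.92 with all 31 genes lower.

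Lists of smooth muscle, endothelial, erythroid and fibroblast genes rose beside the heart genes, while those of skeletal muscle and of cartilage and bone did not pass the test. Smooth muscle genes rose for 7 of 12, fell for 1 and did not pass the test for 4, with the same counts when adjusted over the list alone (camera adjusted p = 0.000135; adjusted p = 0.0819 with an estimated correlation). Acta2, smooth muscle actin, rose by 5.97 ± 0.13 (limma adjusted p = 2.27e-12), but by 0.29 without _x_at and _s_at probe sets (0.144, the highest of a range from 6.44e-14), while Tagln rose by 5.73 ± 0.17 (2.26e-11) and Myl9 by 4.32 ± 0.16 (1.94e-10). Endothelial genes rose for 11 of 18, fell for 3 and did not pass the test for 4, again also when adjusted over the list alone (camera adjusted p = 0.000958; adjusted p = 0.123 with an estimated correlation), among them Icam2 (2.86 ± 0.19, 5.85e-08) and the VEGF receptor gene Kdr (2.48 ± 0.13, 5.87e-09). Erythroid genes rose for 6 of 11 and fell for 0, with 5 not past the test and the same counts adjusted over the list alone (camera adjusted p = 0.000699; adjusted p = 0.084 with an estimated correlation). The embryonic globins Hbb-y, Hbb-bh1 and Hba-x rose by 9.89 ± 0.19 (7.03e-13), 6.66 ± 0.15 (2.4e-12) and 4.48 ± 0.16 (8.39e-11), and Hbb-y by 6.20 without _x_at and _s_at probe sets (4.65e-10). Fibroblast genes rose for 12 of 17, fell for 1 and did not pass the test for 4, with the same counts adjusted over the list alone (camera adjusted p = 6.66e-08; adjusted p = 0.0819 with an estimated correlation), led by the matrix genes Postn (6.27 ± 0.18, 2.38e-11) and Lum (6.16 ± 0.30, 1.98e-09). Skeletal muscle genes rose for 2 of 16, fell for 2 and did not pass the test for 12, also when adjusted over the list alone, with a median of -0.02, a mean of 0.12 and a test pointing up (camera adjusted p = 0.747; adjusted p = 0.834 with an estimated correlation). Acta1 and Tnnt3 rose by 3.99 ± 0.18 (1.15e-09) and 0.63 ± 0.13 (0.00151), while Mylpf fell by 1.79 ± 0.14 (2.51e-07). Genes of cartilage and bone rose for 4 of 11, fell for 4 and did not pass the test for 3, also when adjusted over the list alone, with a median of -0.07, a mean of 0.14 and a test pointing up (camera adjusted p = 0.838; adjusted p = 0.839 with an estimated correlation). The collagen gene Col11a1 rose by 3.46 ± 0.17 (2.56e-09), and Alpl, an alkaline phosphatase gene, fell by 1.98 ± 0.15 (1.73e-07).

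Lists of endoderm genes rose as well. Visceral endoderm and liver genes rose for 11 of 20, fell for 3 and did not pass the test for 6, with 12 up and 3 down when adjusted over the list alone (median 1.39, or 2.13 without dim probe sets and 0.91 without _x_at and _s_at probe sets; camera adjusted p = 7.64e-05; adjusted p = 0.0819 with an estimated correlation). Afp rose by 6.53 ± 0.30 (limma adjusted p = 1.11e-09), the trypsin inhibitor gene Spink1 44.2-fold (3.89e-11), the retinol carrier gene Rbp4 by 5.07 ± 0.27 (5.76e-09) and the transcription factor Sox17 by 6.12 ± 0.14 (2.4e-12), or by 1.35 without _x_at and _s_at probe sets (3.11e-06). Parietal endoderm and basement membrane genes rose for 11 of 14 and fell for 0, with 3 not past the test, and 11 rose and 1 fell when adjusted over the list alone (median 2.41, camera adjusted p = 1.91e-09; adjusted p = 0.084 with an estimated correlation). The keratin genes Krt8 and Krt18 rose by 5.12 ± 0.17 (4.83e-11) and 4.79 ± 0.14 (2.61e-11), and Col4a1 by 4.73 ± 0.13 (2.01e-11).

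Lists of the cell cycle, of glycolysis and of germ cells fell. Of 17 cell cycle genes 14 fell, 0 rose and 3 did not pass the test, with the same counts adjusted over the list alone (median -1.03, camera adjusted p = 8.33e-05; adjusted p = 0.122 with an estimated correlation), led by the cyclin gene Ccnb2 (-1.69 ± 0.15, limma adjusted p = 1.1e-06) and the replication licensing gene Mcm3 (-1.64 ± 0.16, 1.78e-06). Of 14 glycolysis genes 12 fell, 0 rose and 2 did not pass the test, also when adjusted over the list alone (median -0.998, camera adjusted p = 4.84e-05; adjusted p = 0.084 with an estimated correlation), among them Pfkl (-2.58 ± 0.23, 8.48e-07) and Pkm (-1.75 ± 0.16, 1.32e-06). Germ cell genes fell for 7 of 14 and rose for 0, with 7 not past the test and the same counts adjusted over the list alone (camera adjusted p = 0.00178; adjusted p = 0.131 with an estimated correlation), led by Mael, a piRNA pathway gene (-3.08 ± 0.17, 6.86e-09).

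Imprinted genes of both classes moved during differentiation. Paternally expressed genes rose for 12 of 26, fell for 2 and did not pass the test for 12, with the same counts adjusted over the list alone (median 0.16, or 0.31 with cyclic loess, 0.88 without dim probe sets and 0.33 without EB_PSC 1; camera adjusted p = 0.000699; adjusted p = 0.084 with an estimated correlation). Igf2 rose by 5.38 ± 0.16 (limma adjusted p = 2.38e-11), Peg3 by 3.30 ± 0.15 (1.2e-09), Mest by 2.40 ± 0.21 (8.41e-07) and Impact by 0.87 ± 0.17 (0.00071). Plagl1 rose by 4.32 ± 0.23 (4.62e-09) on its _x_at probe set and differed by -0.37 without such probe sets (0.0745, the highest of a range from 6.02e-10). Peg10 and Snrpn both differed by 0.02, with standard errors of 0.19 and 0.15 (0.938 and 0.923), and Dlk1 by 0.15 ± 0.17 (0.489). The probe sets of Peg10 (4.13 in PSC, 4.15 in embryoid bodies) and Snrpn (5.87 and 5.89) were weak there, so a small rise could be missed. Of the 13 paternally expressed genes that were lower in PSC than in ESC, 9 rose in embryoid bodies. Independent lists of these sizes would share 6, a number that leaves out the PSC arrays common to both differences. With those arrays but without any real difference, 100 simulations shared at most 0, so neither number is what real differences and common arrays would give together, and part of the overlap may come from the common arrays. Maternally expressed genes rose for 14 of 25, fell for 6 and did not pass the test for 5, with 15 up and 6 down when adjusted over the list alone (median 0.48, camera adjusted p = 0.00347; adjusted p = 0.084 with an estimated correlation). Asb4 rose by 6.21 ± 0.15 (6.99e-12), Cdkn1c by 2.97 ± 0.21 (8.96e-08), Igf2r by 2.55 ± 0.21 (4.91e-07), Grb10 by 1.55 ± 0.14 (1.05e-06) and Meg3 by 0.72 ± 0.21 (0.0146; 0.0977 without EB_PSC 2 and 7.87e-06, with a rise of 1.14, without _x_at and _s_at probe sets, the ends of the range), while Cobl fell by 2.86 ± 0.17 (1.4e-08) and Rian was at 0.09 ± 0.16 (0.699). Fibroblast genes, with a median of 2.26, rose on the same arrays.

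The X-linked RNA Xist fell by 0.83 ± 0.21 (limma adjusted p = 0.00607), and differed by -0.13 without _x_at and _s_at probe sets (0.49, the highest of a range from 0.000915). Of 7 Y-linked genes 0 were higher in embryoid bodies, 1 was lower and 6 did not pass the test, also when adjusted over the list alone (camera adjusted p = 0.826; adjusted p = 0.834 with an estimated correlation). The 1 was Uba1y (-0.44 ± 0.13, 0.0151), which lost its call without PSC 1 (0.0599) or EB_PSC 2 (0.082) and differed by 0.03 without _x_at and _s_at probe sets (0.898, the highest of a range from 0.0101). Eif2s3y differed by 0.41 ± 0.19 (0.101) and passed the test with cyclic loess (0.036), in a fit of these groups alone (0.0336) and without ESC 2 (0.0266; range 0.0266 to 0.328). Uty differed by 0.14 ± 0.19 (0.598) and Kdm5d by -0.26 ± 0.17 (0.244).

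Over all genes, 7995 of 18194 (43.9%) passed the limma test between embryoid bodies and PSC, 3417 higher and 4578 lower, and 2907 of them differed by at least 2-fold (1557 higher and 1350 lower). With cyclic loess the split was 4185 higher and 3566 lower. Poly-A spike-in controls, which belong to no gene of the cells, were higher by 2.09 on the embryoid body arrays than on the PSC arrays. Groups did not overlap for 62.8% of genes, against 20% by chance. The 8 largest rises were Hbb-y, Ankrd1 (8.71 ± 0.14, adjusted p = 2.34e-13), the small heat shock protein gene Cryab (6.97 ± 0.12, 3.9e-13), Hbb-bh1, Nrp1 (6.55 ± 0.23, 7.3e-11), Afp, Actc1 and Pmp22 (6.41 ± 0.17, 1.28e-11). The 8 largest falls were Calml4 (-4.50 ± 0.13, 2.38e-11), Esrrb, Ano9 (-3.50 ± 0.21), the immediate early gene Fos (-3.45 ± 0.15), Hsf2bp (-3.44 ± 0.17), Mybl2, Pla2g1b (-3.23 ± 0.23) and Gna14 (-3.18 ± 0.18). With the mean of all probe sets, 33 of 153 called genes, counted in the same way, had a difference smaller by over 1.5 times and 2 a larger one, Grb10 (2.33) and Slc22a18 (-0.84). Past the test but smaller were, among others, Cryab (3.98), Tbx20 (2.78), Hand2 (1.97), Myocd (1.52), Myh6 (1.61), Acta2 (2.36), Sox17 (3.73), Lhx1 (1.74), Fgf5 (2.42), Fgf4 (-1.89) and Pfkl (-1.54). So were Igf2 (3.56), Peg3 (1.31), Plagl1 (1.41), Impact (0.52), Sgce (0.43), Cobl (-1.59), Trappc9 (-0.49), Xist (-0.39), Hsf2bp (-1.89), Pla2g1b (-1.46), Gna14 (-1.95) and Pdgfrb (3.01). The call was lost for 3 genes, Uba1y, H2-D1 and Ndn.

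The last comparison set embryoid bodies against ESC for the imprinted genes alone, to see how far the differences of PSC were still present after differentiation, which is here confounded with origin. Paternally expressed genes still stood apart in part: Peg10 was lower than in ESC by -3.61 ± 0.19 (limma adjusted p = 4.84e-09), Impact by -2.55 ± 0.17 (3.43e-08), Kcnq1ot1 by -2.30 ± 0.24 (2.85e-06), Mest by -2.08 ± 0.21 (2.91e-06) and Peg3 by -1.28 ± 0.15 (1.09e-05). Igf2 was higher than in ESC by 4.53 ± 0.16 (8.73e-11). Maternally expressed genes were mostly higher, Asb4 by 6.27 ± 0.15 (5.73e-12), Grb10 by 4.19 ± 0.14 (7.27e-11) and Cdkn1c by 3.70 ± 0.21 (8.73e-09).

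Of 26 paternally expressed genes 10 were lower in embryoid bodies than in ESC, 4 higher and 12 not past the test, or 11 lower and 5 higher when adjusted over the list alone (median -0.19, camera adjusted p = 0.344; adjusted p = 0.548 with an estimated correlation). Of the 9 that were lower in PSC and rose in embryoid bodies, 5 (Peg3, Mest, Impact, Nnat and Sgce) were still below ESC, 2 (Igf2 and Plagl1) were above ESC, and 2 (Inpp5f and Zdbf2) did not pass the test against ESC. Plagl1 was above ESC by 1.01 ± 0.23 (0.00233), but by -0.12 without _x_at and _s_at probe sets (adjusted p = 0.59, the highest of a range from 0.000103). Its call was also lost with the mean of its probe sets (0.28, 0.0557) and without EB_PSC 2 (0.64, 0.0547). Sgce was below ESC by -0.44 ± 0.14 (0.0165), a call that was lost with cyclic loess (0.0984) and without EB_PSC 2 (0.104; range 0.00466 to 0.104). With cyclic loess Inpp5f and Zdbf2 passed the test above ESC (0.37, 0.0211, in a range of 0.0211 to 0.853, and 0.36, 0.0337, in a range of 0.0337 to 0.978). The 4 that did not rise were Peg10, Kcnq1ot1, Mcts2 and Snrpn. Of 25 maternally expressed genes 16 were higher, 3 lower and 6 not past the test, also when adjusted over the list alone (median 0.71, camera adjusted p = 9.11e-05; adjusted p = 0.097 with an estimated correlation). The 3 lower genes were Cobl (-3.62 ± 0.17, 1.24e-09), Trappc9 (-1.001 ± 0.18, 0.00034) and Tssc4 (-0.41 ± 0.15, 0.0405). The call of Tssc4 was lost under 9 of 17 alternatives, among them the removal of EB_PSC 1 (0.173), EB_PSC 2 (0.0849), PSC 2 (0.055), ESC 1 (0.137) or ESC 3 (0.05), in a range of 0.0284 to 0.234. With the mean of all probe sets, Impact (-0.91), Kcnq1ot1 (-0.95), Cobl (-1.95) and Trappc9 (-0.42) differed less from ESC and stayed past the test.

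Genes of the distal part of chromosome 12, a region singled out after its values were seen, were higher in PSC than in ESC. Among genes with a mean above 8, the 42 from Ddx24 to the end of the ordered genes at Cdca7l had a median of 0.88 (quartiles 0.62 and 1.10), against 0.11 for the 178 other such genes of the chromosome and -0.09 for the other autosomes. The 37 dimmer genes of the same part, with means between 6 and 8, had a median of 0.43, against -0.01 for such genes of the other autosomes. Past the limma test, 38 of the 42 were higher and 1 lower. The median was 0.89 without the 3 imprinted genes of the lists, Meg3, Rian and Mirg. The higher values did not begin sharply at Ddx24, which was placed at the largest step of the differences. In the stretch before it, from Npc2 to Cox8c, all genes but Esrrb (-0.39) had a positive difference, from 0.01 (Cpsf2) to 1.14 (Npc2). The 0.11 above pools this stretch with the rest of the chromosome. In embryoid bodies 26 of the 42 were higher than in ESC (median 0.55, against -0.34 for the other autosomes).

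**Figure D3:**
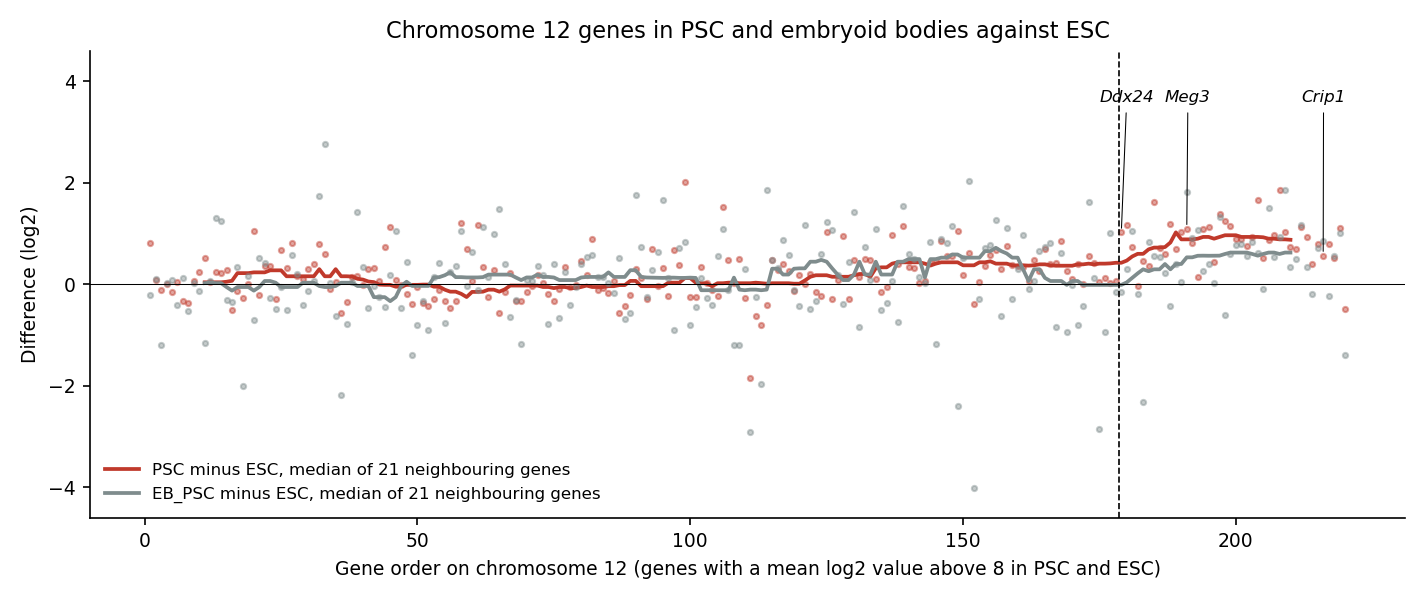
Differences (log2) between PSC and ESC (red) and between embryoid bodies and ESC (grey) for the 220 genes of chromosome 12 with a mean above 8, in their order on the assembly GRCm38.p6, with running medians of 21 genes and a dashed line before Ddx24. Relative to the other autosomes, the 42 genes after the line had a median of 0.97 in PSC and 0.89 in embryoid bodies.

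The control probe sets gave a measure of RNA integrity. The 3' minus 5' difference of Gapdh was -0.03 ± 0.03 in PSC, -0.08 ± 0.02 in embryoid bodies and 0.14 ± 0.05 in ESC (SD, n = 3, 2 and 3), and PSC lay below ESC by -0.17 (exact two-sided permutation p = 0.1). For Actb it was 1.27 ± 0.26, 1.13 ± 0.05 and 0.94 ± 0.22, with a difference of 0.33 between PSC and ESC (exact two-sided permutation p = 0.2). Embryoid bodies and PSC differed with exact two-sided permutation p of 0.3 for Gapdh and 0.7 for Actb. The smallest p these designs allow is 0.1, so none could pass the threshold.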

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

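The exact permutation test of the spike-in controls and the split test of the count of changed genes were chosen after the result was seen, and the split tests of the 3 list values were not. Probe sets for the poly-A spike-in controls, RNAs added to the samples during preparation, stood out because their signal differed between groups although they belong to no gene of the cells. Over 24 probe sets their mean was 7.98 in PSC, 10.07 in embryoid bodies and 8.23 in ESC, a difference of 2.088 between embryoid bodies and PSC (exact two-sided permutation p = 0.1, the smallest value that 2 and 3 arrays allow). The embryoid body arrays were at 10.38 and 9.76, and ESC 2 at 9.20 against 7.66 and 7.82 for the other ESC arrays. The 12 hybridization control probe sets, added later in preparation, differed by 0.50 between embryoid bodies and PSC (exact two-sided permutation p = 0.1). This gap leaves open a difference in sample preparation that coincides with the group and would bear on every difference between embryoid bodies and PSC or ESC, and it was not tested.

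Probe sets that name no gene or several also carried a signal outside the gene tests. Of 10092 such probe sets, 907 changed between PSC and ESC (582 higher and 325 lower, or 8.99%, against 17.5% of probe sets that name 1 gene). Between embryoid bodies and PSC 1975 changed (974 higher and 1001 lower, or 19.6%, against 38.8%). For the 932 that name several genes the annotation lists these genes but not which of them gives the signal. What the others measure is not given in the sources used here.

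The 6 PSC and ESC arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The grouping by cell type gave the largest result in 1 of 10 splits for each of 4 values. It gave 3782 changed genes against at most 0 in another split, 8 lists past the test against at most 4, a paternally expressed median of -0.446 against at most 0.249 in size, and a maternally expressed median of 0.183 against at most 0.128. Each other split mixes PSC and ESC arrays, so real differences enter its spread and lower its count. These splits are therefore no reference for data without a difference.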

How the results depend on the processing

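The removal of chromosome 12 was chosen after the result was seen, and the other 21 of the 22 alternatives were not. Of 6122 values of named or imprinted genes under the alternatives, 5920 kept their side of the threshold, 158 lost and 38 gained a call, and 6 reversed; of 1082 list medians 1045 kept their side, 36 lost a call, 1 gained a call and 0 reversed. Among those that kept their side, 92 values that passed no test changed sign. Array weights, which set how much each array counts, were uneven within ESC, at 3.7 for ESC 3, 0.629 for ESC 1 and 0.464 for ESC 2. That setting therefore rests largely on 1 ESC array. The count of changed genes between PSC and ESC was 5693 with array weights (the cause was not tested) and 2490 to 4142 with 1 array left out. It was 550 at 2-fold or more and 7037 when every probe set was tested, as was 15531 between embryoid bodies and PSC against 2907 at 2-fold or more; these settings count fewer genes or other units. Leaving out 1 array gave 6687 to 8370 for embryoid bodies against PSC, where the lone embryoid body array was assumed to vary like the other groups.

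Lists past the test between PSC and ESC numbered 5 without dim probe sets (fewer genes tested) and 6 to 9 with 1 array left out, and between embryoid bodies and PSC 19 to 20. With an estimated correlation 0 lists passed in either comparison. Unadjusted camera p rose also for lists whose estimated correlation lay below the preset 0.01. For Y-linked genes between PSC and ESC (0.006) it went from 0.00059 to 0.0178. For smooth muscle genes between embryoid bodies and PSC (-0.013) it went from 3.91e-05 to 0.00747. A stronger correlation between genes therefore does not by itself account for the lost calls. With an estimated correlation camera uses only the 5 residual degrees of freedom of the fit, and with the preset one far more. That raises p whatever the correlation of a list, so the lost calls are no measure of correlation alone. How much each part contributes was not tested. With the estimated correlation the paternally expressed median of -0.446 had an adjusted p of 0.17 and the maternally expressed median of 0.183 one of 0.259. The paternally expressed median reached -1.11 without dim probe sets (fewer genes in the list). With 1 array left out the 2 medians ran from -0.532 to -0.361 (adjusted p from 3.68e-09 to 3.69e-06) and from 0.128 to 0.236 (0.00436 to 0.0277). Without chromosome 12 the maternally expressed median was 0.182 (adjusted p = 0.0524). Between embryoid bodies and ESC 7 to 11 paternally expressed genes were lower and 13 to 18 maternally expressed genes higher over the 17 alternatives that give these counts.

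Without _x_at and _s_at probe sets, 6 differences reversed as another probe set took the gene's place: Xist (0.062), Plagl1 (0.252) and Acta2 (0.086) between PSC and ESC, Plagl1 (-0.375) and Uba1y (0.028) between embryoid bodies and PSC, and Plagl1 (-0.123) between embryoid bodies and ESC. Repeated quantile normalization split the genes between PSC and ESC into 2026 higher and 1870 lower, and cyclic loess into 1974 and 1933. Replicate numbers do not pair the samples, since arrays with the same number correlated at -0.25 to 0.22 after removal of group means; a block on them gave 3564 and 7517 changed genes and changed few calls, ending those of Snrpn (0.0516) and Cdk1 (0.0593) between PSC and ESC, of Klf14 (0.0884) between embryoid bodies and PSC, and of Snrpn (0.0606) and Tssc4 (0.093) between embryoid bodies and ESC, where Peg12 gained one (0.0387). Signal over background limits the dim genes: 12413 genes stayed above the filter of 5.44.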

Other observations

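The feeder tests and the tests of distal chromosome 12 were chosen after the result was seen, as was the segment itself. Lists named after earlier embryonic stages also rose in embryoid bodies after 15 days. The streak gene T was not analysed here, and which cells carried these transcripts was not tested. Genes of the primitive streak and early mesoderm rose for 8 of 11, fell for 2 and did not pass the test for 1, with the same counts adjusted over the list alone (median 0.67, or 1.48 without dim probe sets; camera adjusted p = 0.000923; adjusted p = 0.084 with an estimated correlation). Eomes rose by 3.37 ± 0.19 (limma adjusted p = 7.15e-09), Lhx1 by 3.12 ± 0.24 (2.29e-07) and Mixl1 by 1.87 ± 0.13 (8.72e-08). Genes of the primed epiblast rose for 7 of 12, fell for 1 and did not pass the test for 4, also when adjusted over the list alone (median 1.02, or 0.47 with the mean of all probe sets; camera adjusted p = 0.000923; adjusted p = 0.084 with an estimated correlation), led by Fgf5 (4.06 ± 0.21, 4.34e-09). Genes of DNA methylation fell for 9 of 12 and rose for 0, with 3 not past the test and the same counts adjusted over the list alone (median -0.89, camera adjusted p = 0.00166; adjusted p = 0.084 with an estimated correlation). Dnmt3l, a cofactor of the de novo methyltransferases, fell by 2.06 ± 0.17 (4.68e-07), and Tet1, which oxidizes methylcytosine, fell by 2.04 ± 0.15 (9.91e-08). Immediate early and stress genes fell for 9 of 15, rose for 2 and did not pass the test for 4, also when adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.084 with an estimated correlation), with Fosb (-2.30 ± 0.16, 6.65e-08) and Egr1 (-2.29 ± 0.15, 3.63e-08) below Fos in size.

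Macrophage and leukocyte genes rose for 9 of 16, fell for 2 and did not pass the test for 5, with the same counts adjusted over the list alone (camera adjusted p = 0.0293; adjusted p = 0.603 with an estimated correlation). Their call was also lost without EB_PSC 2 (0.497), with cyclic loess (0.0569) and without dim probe sets (0.35), in a range of 9.14e-06 to 0.603. Mrc1 rose by 2.21 ± 0.14 (limma adjusted p = 2.19e-08) and Cd68 fell by 2.29 ± 0.14 (1.95e-08). Neuroectoderm genes rose for 7 of 18, fell for 6 and did not pass the test for 5, also when adjusted over the list alone, with a median of -0.04, a mean of 0.08 and a test pointing up (camera adjusted p = 0.666; adjusted p = 0.71 with an estimated correlation). Gap43 rose by 2.87 ± 0.23 (2.98e-07) and Olig2 fell by 2.67 ± 0.33 (1.79e-05). Genes of chromosome X rose for 192 of 617, fell for 103 and did not pass the test for 322, or rose for 193 and fell for 104 when adjusted over the list alone (median 0.04, or 0.02 to 0.21 over the alternatives that moved it by over 1.5 times; camera adjusted p = 0.000966; adjusted p = 0.084 with an estimated correlation). Among genes with a mean above 8 in PSC and ESC, 187 of them on chromosome X, the X chromosome was also set against autosomes. Relative to autosomes and to the mean of the ESC arrays, its median was 0.457 and 0.497 in the embryoid body arrays and 0.073 to 0.115 in the PSC arrays. Without that minimum the gap was smaller. Over all 617 genes of chromosome X the median of embryoid bodies minus ESC was 0.087, against -0.0733 over all genes.

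Lower paternally expressed transcripts in PSC fit cells without a paternal genome, and 2 technical explanations were set against that. Among 10000 random gene sets matched on mean signal the lowest median was -0.276, against -0.446 for the list, so signal level or normalization is unlikely to give such a fall. Feeder fibroblasts in the ESC cultures could add paternally expressed transcripts, and the fibroblast median lay at -0.617. Mest needs the largest share, and if it stood at the highest value of any array in feeder cells, at least 6.09% of the ESC RNA would have to come from them. Feeder RNA and the missing paternal genome cannot be told apart here, because the feeder profile and its share were not measured. Other differences between the PSC and the R1 line are confounded with genome origin too.

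The rise of 9 of these genes in embryoid bodies, which for Plagl1 is not seen without _x_at and _s_at probe sets, could be regulation of maternal alleles during differentiation or feeder cells carried into the cultures. If feeder cells carried Eif2s3y at about the ESC level, the excess of its probe set would put their share at 1.61% at most. Of the 9 genes, 2 (Igf2 and Plagl1) would need a larger share even at the highest value of any array, Igf2 at least 20.4%. For Plagl1 this rests on its _x_at probe set. Xist, which female feeder cells would add, fell by 0.83 on an _s_at probe set. The Eif2s3y probe set lay below the limit for dim probe sets in PSC and in embryoid bodies, and the sex and profile of any feeder cells are not given in the sources used here, so these values exclude nothing. That keeps both explanations open, and they cannot be told apart here.

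The higher signal of distal chromosome 12 may reflect a difference in copy number between the PSC and ESC lines, such as a gain in PSC or a loss in R1. When the differences were shuffled 1000 times among autosomal genes of like signal, the highest median of any 42 neighbouring genes was 0.278, against 0.88 for the segment, which makes signal level or normalization unlikely. Strain variants under single probe sets would touch scattered genes. The lower quartile of the segment was 0.622, but the segment was chosen for high differences in these same values, so this quartile does not decide the question. A copy number difference would remain in embryoid bodies, and when the segment was chosen again without 1 ESC array, its median in embryoid bodies against that array was at least 0.751 relative to other autosomes. Strain variants under probe sets would also remain in embryoid bodies, so this value does not tell them from a copy number difference. With 1 ESC line a gain and a loss look alike, and a regulatory difference between strains, which would also remain, was not tested.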
